A study of Mus musculus with 4 samples.

How the data were processed

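Whole kidneys microdissected from mouse embryos at embryonic day 15.5 were measured by RNA-seq in 4 libraries. Per the labels' protocols, RNA was extracted with a phenol reagent and a column kit, RNA passing an integrity threshold was used, poly(A) RNA was isolated on magnetic beads, and libraries were made by RNase III fragmentation and ligation of Ion Torrent adaptors. Samples were grouped by the genotype label into mutant (HoxB7-Cre with 1 LacZ and 1 floxed Hnf1b allele, 2 libraries) and control (1 wild-type and 1 floxed allele, 2 libraries). The titles use short codes for the groups that read as heterozygous and wild-type, and the genotype and source labels were followed. Replicate numbers were given in the order of the records, so no pairing was tested.

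The authors deposited 1 table of read counts per gene, which is the input of every main result. Per the file headers it lists 1 RefSeq accession, coordinates and a GC content in percent for each gene, and per the submitters' processing notes the genome build was mm9 and edgeR was used, with no version and no stated role. The aligner, the counting rule and whether strand was used are not given in the sources used here, so antisense and overlapping genes and near-identical gene copies can share reads. The counts are whole numbers over 21065 rows with a different total in each library, and 1004 rows have no count in any library. No mitochondrially encoded gene is among the rows analysed here, so the list of 10 such genes had 0 members to test. A second deposited table gives the authors' normalized values as whole numbers, treated here as a score. In each library they equal the counts times 1 constant apart from rounding, with constants of 1.04 (mutant 1), 0.776 (mutant 2), 1.11 (control 1) and 1.18 (control 2), checked over genes with at least 1000 counts. They entered only 1 alternative. GC content, in percent as deposited by the authors, entered only a check. Starts in the file fit a count from 0 (5446 genes, against 474 that fit a count from 1, when spans were compared with a RefSeq table), so printed starts are raised by 1. The RefSeq table is of assembly GRCm38, another build, and gave only names, synonyms and that check. By accession 16086 genes matched it. Transcript lengths for a later check came from GENCODE transcripts, matched through RefSeq identifiers, for 16070 tested genes.

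Depth was 27893924, 39244784, 25781045 and 26553728 counts in mutant 1, mutant 2, control 1 and control 2. The 2 mutant libraries differed by a chi-square of 30.2 per degree of freedom and the 2 controls by 19.9, far more than sampling noise, so all were kept as separate samples. The biological coefficient of variation was 0.157. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, which left 16179, scaled by TMM, and tested with estimateDisp, glmQLFit with its installed defaults and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. CPM values are scaled by TMM, and their error is the SD over 2 libraries. Gene lists with at least 5 tested members were tested with camera on the edgeR object, with a preset correlation of 0.01. They were also tested with an estimated correlation and with fry, which have little power with 2 libraries per group. The lists cover ureteric bud tip and trunk, urothelium, principal and intercalated cells, polarity, junctions, basement membrane, HNF1B targets, cystic disease and cilium, nephron progenitors, renal vesicle, proximal tubule, loop and distal tubule, podocytes, stroma, endothelium, leukocytes, erythroid cells, adrenal, gonad, neurons, skeletal muscle, cell cycle, p53, Wnt response, immediate early genes, hypoxia, injury, cholesterol and mitochondrially encoded genes. Sex-linked genes were given per library only. Lists, tests, thresholds and alternatives, apart from those named as chosen later, were fixed before the data were examined.

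The rule for named genes, also fixed then, took Hnf1b; up to 12 lower and 12 higher genes with an adjusted p under 0.05, no overlap between the groups in CPM and a mean of at least 2 CPM, ranked by fold change, without predicted genes, pseudogenes or sex-linked genes; from each list up to 4 members of lowest p and any that passed; and a fixed set of genes of bud branching, HNF1B targets and nephron markers. Gatm and Ace2 stand outside the rule and were named after their values were seen.

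The steps were tested on simulated data made from the real means, library sizes and dispersions of the 16179 genes for mutant against control, with 200 genes changed. The test recovered 72% of 100 genes changed by 2-fold and 89% of 100 changed by 4-fold, and 11.0% of its calls were unchanged genes, above the nominal 5%. With no gene changed it made 5 calls. A list of changed genes, all lowered, had a camera p of 2.81e-52 and an unchanged one of 0.763. The simulated genes were drawn independently, so this does not test camera on correlated lists. The estimated correlation was 0.756 for the proximal tubule list and 0.996 for the muscle list.

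The alternatives were scaling by DESeq2 size factors, upper quartile or library size only, removal of haemoglobin genes, no low-count filter, a filter of 1 CPM in 2 libraries, each library left out in turn, DESeq2 1.42.0, edgeR's exact test, a robust quasi-likelihood fit, limma-voom (limma 3.58.1), limma-trend on log2(normalized value + 1) of the deposited normalized table, an adjusted p of 0.1, a fold of at least 2, and lists without their called members. The quasi-likelihood fit with legacy = FALSE and a GC content offset, a loess of span 0.3 of each library's log counts on GC, were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.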

Results

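Poly(A) RNA of whole embryonic mouse kidneys was sequenced at stage E15.5 in 4 libraries on a C57BL/6 background. The 2 mutant libraries came from kidneys that carried a Cre recombinase driven by HoxB7 regulatory sequences, 1 LacZ allele and 1 floxed allele of Hnf1b. The 2 control libraries carried 1 wild-type and 1 floxed allele of Hnf1b, and their genotype label names no Cre. HoxB7-Cre is active in the Wolffian duct and its derivative, the ureteric bud, which forms the collecting ducts and the epithelium of the pelvis and ureter. The nephron tubules arise from another lineage, the mesenchyme around the bud, in which the labels imply no recombination, so that these cells in the mutants had 1 LacZ and 1 floxed allele. HNF1B is a homeodomain transcription factor of kidney, liver and pancreas epithelia, and the series title sets its question as the part HNF1B plays in epithelial organisation and polarity while the ureteric bud branches and the collecting duct forms. The libraries held 27893924 counts (mutant 1), 39244784 counts (mutant 2), 25781045 counts (control 1) and 26553728 counts (control 2), and between 15775 and 16288 genes had at least 10 counts. The labels do not say whether the replicates were separate embryos or litters, so p-values measure only the spread between these samples. Replicate numbers name the libraries and pair nothing.

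Hnf1b itself (NM_009330, chromosome 11, 83664371 to 83719419 on mm9, plus strand, a protein-coding gene) had 85.1 ± 3.43 CPM (TMM-normalised read count; SD, n = 2) in mutant kidneys and 113 ± 19.6 CPM (SD, n = 2) in control kidneys. Its levels were 87.5 CPM in mutant 1, 82.7 CPM in mutant 2, 98.9 CPM in control 1 and 127 CPM in control 2. The log2 fold change was -0.41 (SE 0.13), and edgeR's quasi-likelihood test did not call it (Benjamini-Hochberg adjusted p = 0.149). It was -0.23 without control 2 and -0.58 without control 1. Gene-level counts pool reads over the whole transcript, including any part that recombination leaves in place. They also pool nephron cells that the Cre does not reach, which in mutants carry 1 LacZ and 1 floxed allele. What the LacZ allele adds to these counts was not tested. The Hnf1b value is therefore a weak check of the labels.

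Mutant kidneys had far more genes at lower than at higher levels, and the lower genes included 22 of the 24 members of the proximal tubule list. Of 16179 genes tested, 572 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 492 lower and 80 higher in mutants. Of these, 302 of the lower and 32 of the higher genes differed by at least 2-fold. An unadjusted p under 0.05 in the same test was held by 3136 of the 16179 genes, the background for such counts in the lists below. By the rule for named genes, the 12 strongest lower genes were Cyp2d26, Gsta1, Upk3a, Spp2, Gsta2, Fbp1, Slc5a8, Slc22a12, Slc22a13, Mettl7b, Slc17a1 and Cyp2j5. Of these, Spp2, Fbp1 and Slc17a1 belong to the proximal tubule list and Upk3a to the urothelium list. Cyp2d26, a cytochrome P450, averaged 0.698 ± 0.541 CPM in mutants against 42.0 ± 5.73 CPM in controls (SD, n = 2 each; log2 fold change -5.82, SE 0.38, edgeR adjusted p = 0.000217). Slc22a12, the urate transporter URAT1, averaged 1.81 ± 0.721 CPM against 49.5 ± 11.9 CPM (SD, n = 2 each; log2 fold change -4.75). Gsta1 and Gsta2 are glutathione transferases with near-identical sequence, so the split of reads between them is uncertain. The 12 strongest higher genes were Krt5, Krt14, Krt4, Krt17, Krt15, Pkp1, Cxcl13, Cnmd, Gabrp, Plekhs1, Cldn23 and Ltbp2. Pkp1 did not pass in 5 of the 13 other fits that kept the 4 libraries, nor without control 1 or control 2. Cldn23 did not pass with library size scaling or limma-voom, and Krt14 and Krt4 did not pass with limma-voom. The number of calls moved strongly with the library left out, with fewer calls without a control than without a mutant. Such a fit takes its variance from the remaining pair alone. The mutant pair differed by a chi-square of 30.2 per degree of freedom and the control pair by 19.9. The counts therefore cannot separate reliance on 1 library from a change in the variance estimate. The median log2 fold change of the proximal tubule list was -2.48 without control 2, against -2.80 with all 4 libraries. Of the 80 named genes that passed, 53 did not pass without control 2, 24 without control 1, 2 without mutant 1 and 1 without mutant 2, while 27 passed in all 4 of these fits.

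Proximal tubule genes fell together. Of the 24 members of the list fixed for this segment, 22 were lower, none was higher and all 24 had a negative fold change, with a median log2 fold change of -2.80. Slc34a1, the sodium-phosphate cotransporter NaPi-IIa, averaged 12.3 ± 8.94 CPM in mutants and 240.1 ± 25.1 CPM in controls (SD, n = 2 each; log2 fold change -4.26, SE 0.42, edgeR adjusted p = 0.00116). Its log2 fold change was -3.69 without mutant 1 and -5.33 without mutant 2. Slc22a6, the organic anion transporter OAT1, averaged 2.68 ± 0.224 CPM against 50.8 ± 16.2 CPM (log2 fold change -4.25, SE 0.25). The endocytic receptor genes Lrp2 (megalin) and Cubn (cubilin) fell by 2.34 and 2.56 on the log2 scale, and Hnf4a and Hnf1a, transcription factors of this segment, fell by 2.20 and 1.51. Fbp1 and Pck1, gluconeogenic enzymes, had log2 fold changes of -4.89 and -4.00. Miox had 0 and 3 counts in the mutant libraries and 65 and 91 in the controls. Gatm (log2 fold change -1.04) and Ace2 (-0.11) did not pass. Adjusted over the list alone, 23 members passed. The robust fit called 20 members and did not call Slc34a1 or Pck1. The list was lower in camera with its preset correlation (adjusted p = 2.51e-108), with an adjusted p of 0.397 with an estimated correlation. Without control 2, 16 of the 24 members passed and the median was -2.48. Without mutant 1, the library with skeletal muscle transcripts described further on, the median was -2.53.

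Genes of the loop of Henle and distal tubule were lower in part. Of 18 members tested, 8 were lower and none higher, with a median log2 fold change of -0.67. Slc12a1, the NKCC2 cotransporter of the thick ascending limb, averaged 74.4 ± 0.257 CPM in mutants against 198 ± 35.5 CPM in controls (SD, n = 2 each; log2 fold change -1.41, SE 0.14, edgeR adjusted p = 0.00109). The potassium channel gene Kcnj1 fell by 2.77 and Umod, which encodes uromodulin, by 2.23 on the log2 scale. Cldn10, Cldn19, Bsnd, Clcnkb and Slc12a3 were the other lower members, and the last of these, which encodes the thiazide-sensitive cotransporter, did not pass under 4 of the 13 other fits. Clcnkb did not pass with library size scaling. Adjusted over the list alone, 12 members passed lower and 1 higher. The camera adjusted p was 1.75e-10, with an adjusted p of 0.397 with an estimated correlation. Without control 2, 1 of the 18 members passed.

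With all 4 libraries, edgeR's quasi-likelihood test called no member in the lists for the other nephron compartments. The 15 podocyte genes had a median log2 fold change of -0.08, and 3 of them had an unadjusted p under 0.05. Wt1, a podocyte and progenitor transcription factor, averaged 293 ± 0.714 CPM in mutants and 213 ± 2.40 CPM in controls (log2 fold change 0.46, SE 0.11, edgeR adjusted p = 0.0694), and DESeq2 and edgeR's exact test did call it higher. The 16 nephron progenitor genes had a median of 0.07, with 5 at an unadjusted p under 0.05. Six2, which marks the progenitors, averaged 69.9 ± 10.5 CPM against 87.4 ± 3.06 CPM (log2 fold change -0.32, edgeR adjusted p = 0.212), and was called lower without mutant 2. The 16 genes of the renal vesicle to the S-shaped body had a median of 0.06, with 3 at an unadjusted p under 0.05, and Wnt4 of this list had a log2 fold change of 0.02 (SE 0.10). DESeq2, edgeR's exact test, the robust fit, limma-voom and limma-trend on the deposited normalized values also called no progenitor or vesicle member. Without mutant 1, 2 podocyte genes were lower, and without mutant 2, 1 progenitor gene was lower and 1 higher and 1 vesicle gene was higher.

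Genes of both collecting duct cell types were lower in part; the difference between the lists was not tested. Of 15 intercalated cell genes, 9 were lower and none higher, and all 15 had a negative fold change with a median of -1.19. Foxi1, the transcription factor needed for intercalated cells, averaged 4.02 ± 0.0932 CPM in mutants against 14.6 ± 3.38 CPM in controls (SD, n = 2 each; log2 fold change -1.85, SE 0.23, edgeR adjusted p = 0.00316). Atp6v0a4, a subunit of the proton pump, fell by 2.21, the transporter gene Slc4a9 by 1.36 and the carbonic anhydrase gene Car2 by 1.19 on the log2 scale, and Atp6v1b1, Atp6v0d2, Rhcg, Car12 and Oxgr1 also passed. Car12 did not pass on the deposited normalized values, nor Oxgr1 with library size scaling. Of 11 principal cell genes, Aqp2 and Scnn1a were lower and none was higher, with a median of -0.41. This median was -0.20 without mutant 1 and -0.56 without mutant 2. Aqp2, the vasopressin-regulated water channel, averaged 2.39 ± 1.13 CPM against 11.2 ± 4.12 CPM (log2 fold change -2.24, SE 0.38, edgeR adjusted p = 0.0165). Scnn1a, a subunit of the epithelial sodium channel, had a log2 fold change of -1.77. Adjusted over each list alone, 12 and 3 members passed. The camera adjusted p was 3.87e-16 for intercalated and 0.00034 for principal cells, with an adjusted p of 0.397 for both with an estimated correlation. Without control 2, 1 intercalated and 0 principal cell genes passed in edgeR's test, and without control 1 the counts were 4 and 2. Without mutant 2, 5 principal cell genes passed, and without mutant 1 it was 3. Over the 4 libraries 13 intercalated and 7 principal cell genes had an unadjusted p under 0.05.

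Among genes of the branching ureteric bud, the tip program did not pass. The 14 tip genes had a median log2 fold change of 0.08 with none called and 2 at an unadjusted p under 0.05, and none of the 5 other tests called a member. Ret, the receptor for GDNF, averaged 69.1 ± 3.79 CPM in mutants and 52.5 ± 1.55 CPM in controls (log2 fold change 0.40, SE 0.11, edgeR adjusted p = 0.0989). Gfra1, Wnt11, Etv4 and Etv5 had log2 fold changes of 0.06, 0.04, 0.00 and 0.13. Of 18 genes of the bud trunk and early ureteric epithelium, 3 were lower and none higher. Krt7, a simple epithelial keratin, fell by 0.83, Cdh16, the kidney-specific cadherin, by 0.72 and Wnt9b, which the bud secretes to induce nephrons, by 0.59 on the log2 scale. Cdh16 did not pass without mutant 1, and neither Cdh16 nor Wnt9b passed with the GC content offset. Wnt7b had a log2 fold change of -0.52 (edgeR adjusted p = 0.0612) and was called lower by DESeq2, edgeR's exact test, the robust fit, the CPM filter and without mutant 2. Pax2 had a log2 fold change of -0.01 and Lhx1 of 0.16. Adjusted over the list alone, 6 trunk genes passed. The camera adjusted p was 0.00599, with an adjusted p of 0.397 with an estimated correlation and 0.0709 without mutant 1, and no trunk member passed in edgeR's test without control 1 or without control 2, while 5 passed without mutant 1 or mutant 2. Over the 4 libraries 6 trunk members had an unadjusted p under 0.05.

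Of 20 genes described in the literature as HNF1B targets, 8 were lower and none higher, with a median log2 fold change of -0.36. These were Hnf4a, Umod, Tmem27, Kif12, Pkhd1, Cys1, Cdh16 and Wnt9b. Pkhd1, the gene of recessive polycystic kidney disease, averaged 27.9 ± 3.02 CPM in mutants against 48.7 ± 6.47 CPM in controls (SD, n = 2 each; log2 fold change -0.80, SE 0.15, edgeR adjusted p = 0.0224). Cys1, which encodes the cilium protein cystin, fell by 0.88, while Pkd2 had a log2 fold change of 0.20 and did not pass. Hnf4a, Umod and Tmem27 are also members of the proximal tubule or loop lists. The camera adjusted p was 2.05e-06, with an adjusted p of 0.397 with an estimated correlation, and 10 members passed lower and 1 higher when adjusted over the list alone. Of 17 genes of cystic kidney disease and the primary cilium, 5 were lower (Umod, Pkhd1, Cys1, Glis2 and Glis3) and none higher, and the list did not pass (camera adjusted p = 0.102). Glis2 did not pass with the GC content offset or on the deposited normalized values, nor Glis3 on those values, with limma-voom or with no filter, so that 3 cystic genes passed on the deposited values and 4 with limma-voom. Without control 1, 5 of the 20 targets and 3 of the 17 cystic genes passed. Without control 2, 1 of the targets and none of the cystic genes passed in edgeR's test, and 12 and 7 of them had an unadjusted p under 0.05 over the 4 libraries.

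Of 20 apical-basal polarity genes, 2 were lower and none higher, with a median log2 fold change of -0.13. Slc9a3r1, the scaffold NHERF1 beneath the apical membrane, averaged 61.8 ± 0.992 CPM in mutants against 107 ± 11.4 CPM in controls (SD, n = 2 each; log2 fold change -0.80, SE 0.11, edgeR adjusted p = 0.00707). Llgl2, of the basolateral Scribble group, averaged 44.3 ± 4.77 CPM against 72.3 ± 1.57 CPM (log2 fold change -0.71, SE 0.12, edgeR adjusted p = 0.0165). Whole-kidney counts do not tell in which cells these 2 genes fell, and proximal tubule genes fell in the same kidneys. Crb3, Prkcz and Pard6b, of the apical Crumbs and Par complexes, had log2 fold changes of -0.67, -0.62 and -0.45 with edgeR adjusted p of 0.0649, 0.0801 and 0.0987. DESeq2 called 4 polarity genes lower, Crb3 and Prkcz among them, and edgeR's exact test and the robust fit each called 3, with Crb3. Crb3 also passed without mutant 2, and Prkcz and Pard6b without mutant 1. Adjusted over the list alone, 6 polarity genes passed, and the list did not pass (camera adjusted p = 0.0673). Neither Slc9a3r1 nor Llgl2 passed without control 2, and the number of called polarity genes was 0 without control 2, 1 without control 1, 4 without mutant 1 and 3 without mutant 2, with 8 at an unadjusted p under 0.05 over the 4 libraries. That test called no member among 20 epithelial junction genes (median -0.11) or 25 basement membrane genes and receptors (median 0.01), of which 4 and 7 had an unadjusted p under 0.05. DESeq2, edgeR's exact test and the robust fit each called 1 junction gene lower. In the basement membrane list DESeq2 called 2 genes in each direction, the exact test 1 lower and the robust fit 0, while limma-voom and limma-trend on the deposited normalized values called 0 in either list. Without mutant 1, 1 junction gene was lower and 1 basement membrane gene higher, and without mutant 2 the counts were 1 and 2. Cdh1, which encodes E-cadherin, had a log2 fold change of -0.24 (SE 0.12).

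Krt5, Krt14, Krt15, Krt4 and Krt17 rose in mutant kidneys, while Upk3a fell. Of 9 tested genes of urothelium and pelvis, Krt5, Krt14 and Krt15 were higher and Upk3a lower. Krt5 (chromosome 15, 101537501 to 101543322 on mm9), a keratin of basal cells, was at 70.9 CPM in mutant 1, 27.4 CPM in mutant 2, 0.226 CPM in control 1 and 0.276 CPM in control 2 (log2 fold change 7.59, SE 0.58, edgeR adjusted p = 0.000364). Krt15 averaged 41.4 ± 27.2 CPM in mutants against 2.12 ± 0.776 CPM in controls, and Krt14 9.12 ± 8.06 CPM against 0.171 ± 0.131 CPM (SD, n = 2 each; log2 fold changes 4.28 and 5.68). Krt4 and Krt17, outside the list, had log2 fold changes of 5.32 and 5.24. Upk3a, which encodes a plaque protein of the urothelial surface, was at 0.0701 CPM in mutant 1, 1.80 CPM in mutant 2, 34.8 CPM in control 1 and 33.6 CPM in control 2 (log2 fold change -5.08, SE 0.67, edgeR adjusted p = 0.00479). With 1 library left out its log2 fold change ranged from -8.85 to -4.24. Among other higher genes, the chemokine gene Cxcl13 rose by 2.18 (SE 0.38) and Gabrp, a GABA receptor subunit, by 1.97 (SE 0.26) on the log2 scale. These 5 keratins all had higher levels in mutant 1 than in mutant 2, and mutant 1 also carried skeletal muscle transcripts; without mutant 1 the log2 fold changes of Krt5 and Krt15 were 6.75 and 3.38. The urothelium list was higher in camera (adjusted p = 8.83e-05), with an adjusted p of 0.617 with an estimated correlation and 0.0936 without mutant 1, where the median log2 fold change went from 0.84 to -0.15, and 4 members passed higher and 1 lower when adjusted over the list alone. Higher calls in the list numbered 1 without control 2 and 5 without mutant 2. Without control 2, Krt14, Krt4, Krt15 and Upk3a did not pass, and the robust quasi-likelihood fit called none of these 4 nor Krt5.

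Markers of tissues outside the kidney set mutant 1 apart. The 11 skeletal muscle genes summed to 1759 CPM in mutant 1 against 39.2 CPM in mutant 2, 39.5 CPM in control 1 and 36.9 CPM in control 2. Actc1, an actin of striated muscle, was at 265 CPM in mutant 1 and at 3.52, 1.77 and 2.05 CPM in mutant 2, control 1 and control 2. No muscle member passed (median log2 fold change 4.99, with 11 at an unadjusted p under 0.05), although all 11 passed higher when adjusted over the list alone, edgeR's exact test called 10 and DESeq2 called 2, and limma-voom, the robust fit and limma-trend on the deposited normalized values called 0. Without mutant 2, 13 muscle genes were tested and all 13 passed. The list passed in camera (adjusted p = 2.3e-05), with an adjusted p of 0.766 with an estimated correlation and 0.71 without mutant 1. Mutant 1 also had few transcripts of Y-linked genes, with 27 counts of Ddx3y (0.946 CPM) against 101 CPM in mutant 2, 67.2 CPM in control 1 and 75.8 CPM in control 2. Eif2s3y, Kdm5d and Uty had 7, 25 and 40 counts in mutant 1, against 1930, 2701 and 1721 in mutant 2. Control 1 had 1273, 1661 and 848 counts of them and control 2 had 1073, 1476 and 923. These Y-linked genes argue against male tissue as the main source of mutant 1, so embryo sex was not balanced between the groups. Xist, also in the sex-linked list, had 0 counts in all 4 libraries, so Xist itself does not tell the sex of mutant 1. Haemoglobin genes took 1.07%, 0.694%, 1.21% and 1.84% of counts in mutant 1, mutant 2, control 1 and control 2.

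The lists for other cell types of the kidney and its surroundings had few calls. With all 4 libraries, edgeR's quasi-likelihood test called none of 17 stromal, 14 leukocyte, 12 erythroid, 9 adrenal, 5 gonadal or 12 neural genes, whose medians were 0.03, 0.08, -0.28, 0.46, -0.00 and 0.36; the erythroid median was 0.17 with the haemoglobin genes left out. In that order 1, 2, 3, 4, 1 and 1 of these genes had an unadjusted p under 0.05. On the same libraries DESeq2 and edgeR's exact test each called 1 stromal and 1 leukocyte gene higher and 1 erythroid gene lower, and the robust fit called 1 leukocyte gene higher. Without mutant 2, 4 stromal, 2 leukocyte and 2 neural genes were higher and 1 erythroid gene lower. Without mutant 1, 3 erythroid genes and 1 adrenal gene were lower, and without control 1, 1 erythroid gene. Of 15 endothelial genes, Eng, which encodes endoglin, was lower (log2 fold change -0.46, edgeR adjusted p = 0.047) and did not pass in any of the 4 fits that left out a library, nor in 5 of the 13 other fits. The endothelial list did not pass (camera adjusted p = 0.373) except without mutant 1 (adjusted p = 0.0144), where 2 members were lower, and the erythroid list did not pass (0.74) except without control 1 (0.0348).

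Stress and growth lists were mixed. Of 12 genes of the p53 response, Pmaip1 rose by 1.76 (SE 0.26) and Sesn2 fell by 0.88 on the log2 scale. Of 13 genes of tubular injury and fibrosis, Lcn2, which encodes the injury marker NGAL, rose by 1.67 (SE 0.26), while Spp1, which encodes osteopontin and is expressed in tubules, had a log2 fold change of -2.73 (SE 0.37), Tgfb1 of -0.62 and Clu of -0.56, all 3 lower. Ndrg1 was the lower member of 14 hypoxia genes (log2 fold change -1.17, SE 0.12, edgeR adjusted p = 0.00123) and passed in every alternative fit, with 2 hypoxia genes called without mutant 2. Pmaip1, Sesn2, Lcn2, Spp1, Tgfb1 and Clu did not pass without control 2, and Pmaip1, Sesn2, Lcn2 and Tgfb1 did not pass without control 1. Clu did not pass in 4 of the 13 other fits that kept all libraries, nor Tgfb1 with the GC content offset. Without mutant 1, 3 injury genes were higher and 2 p53 genes lower, and without mutant 2, 2 p53 genes were higher. With all 4 libraries, edgeR's quasi-likelihood test called none of 16 cell cycle, 12 Wnt response, 14 immediate early and heat shock or 14 cholesterol genes (medians 0.13, -0.04, -0.09 and 0.01), with 4, 1, 5 and 2 at an unadjusted p under 0.05. DESeq2 and edgeR's exact test each called 1 cell cycle gene higher, and without mutant 1, 1 cell cycle gene was higher and 1 cholesterol gene lower. The cell cycle list had a camera adjusted p of 0.0517, and passed as higher under 3 of the other scalings and filters and without mutant 1 or control 2. Median, mean and camera direction differed in sign for the injury list (median 0.04, mean 0.10, camera lower), the hypoxia list (median 0.01, mean -0.04, camera lower) and the gonadal list (median -0.00, mean 0.12, camera higher).

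Over all 30 lists tested, camera with its preset correlation called 6 lower and 2 higher. With an estimated correlation it called 0 of 30, with 2 at an unadjusted p under 0.05. The fry test called 0, with 8 at an unadjusted p under 0.05. Even the proximal tubule list, with all 24 members below 0, had unadjusted p of 0.0284 (camera, estimated correlation) and 0.0163 (fry). With 2 libraries per group these tests had little power, so their lack of calls does not by itself count against a list. The 17 lists with no called member held 242 tested members, counted once per list, of which 59 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Over the same lists DESeq2 called 4 members lower and 8 higher, edgeR's exact test 3 and 14, the robust fit 1 and 1, and limma-voom and limma-trend on the deposited normalized values 0 in either direction.

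**Figure D1:**
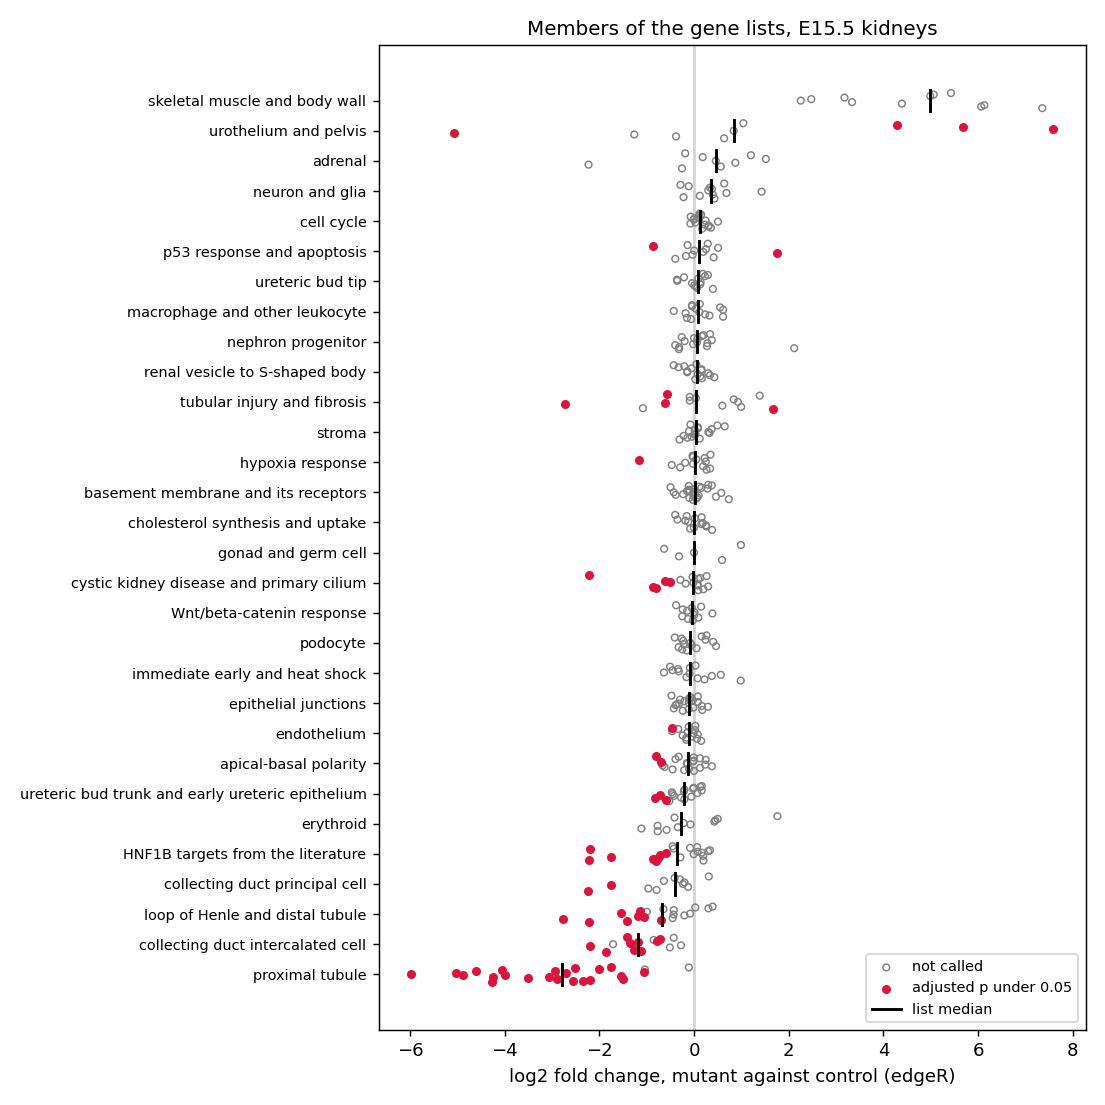
Log2 fold change of each tested member of the 30 gene lists (horizontal axis, mutant against control, edgeR; lists on the vertical axis, ordered by median). Filled red points passed an adjusted p of 0.05, open grey points did not, and black bars are list medians; the proximal tubule list has a median of -2.80, and the muscle list lies far to the right, with a median of 4.99 and no called member.

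**Figure D2:**
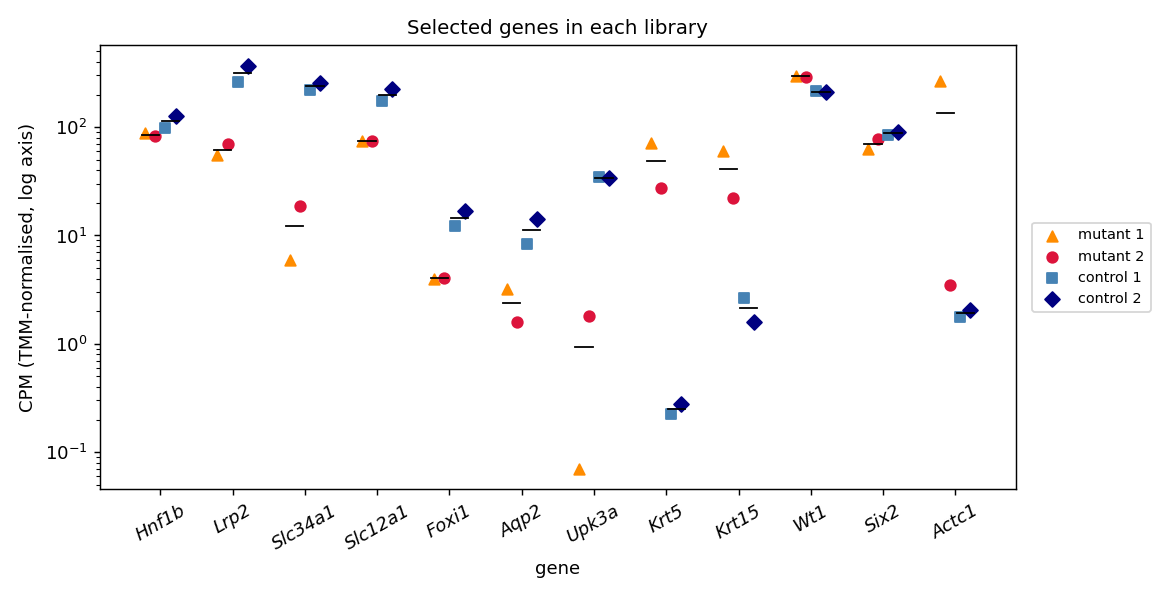
CPM of 12 genes in each of the 4 libraries (vertical axis, log scale; genes on the horizontal axis). Points are libraries and black bars the means of the 2 mutant and the 2 control libraries; the Lrp2 means are 62.1 CPM in mutants and 314 CPM in controls, and Actc1 is high in mutant 1 alone.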

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

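Of the alternatives, only the GC content offset and the fit with legacy = FALSE were chosen after the data were seen; the planned fit with legacy = TRUE is the installed default and so the result reported. No gene called in the reported test changed sign in any alternative, and the Hnf1b fold change stayed negative and uncalled in all, from -0.58 without control 1 to -0.23 without control 2. The Pkp1 fold change was 1.72 without mutant 1, against 2.83. Leaving out 1 library moved the calls from 109 to 896 lower and from 2 to 481 higher. The extremes are control 2 left out (109 lower, 2 higher), mutant 1 left out (896 lower) and mutant 2 left out (481 higher). Leaving out a library leaves 1 group with a lone sample assumed to vary like the other group. DESeq2 called 764 lower and 271 higher, edgeR's exact test 717 lower and 224 higher, the robust fit 614 lower and 145 higher, an adjusted p of 0.1 792 lower and 254 higher, and a fold of at least 2 302 lower and 32 higher. The last 2 follow from their construction; for the others the cause was not tested. All other alternatives gave 421 to 535 lower and 57 to 91 higher genes. The GC offset called 460 lower and 66 higher, of which 416 and 47 were among the 492 and 80 reported. Over all tested genes, log2 fold change and GC content had a Spearman correlation of -0.27. Median GC content was 48.2% for the lower genes, 42.6% for the higher genes and 46.0% for all tested genes. The GC check on the proximal tubule list below covers that list alone.

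Lists called higher ranged from 1 to 3 when 1 library was left out (1 without mutant 1). With an estimated correlation and with fry 0 lists were called lower and 0 higher, and with called members left out 1 lower (intercalated cells) and 1 higher (muscle), from fewer members; the proximal tubule list then had too few members left to test. Among named genes, values near 0 changed sign without a call: Etv4 was -0.0031 with upper quartile scaling and -0.001 with the CPM filter, and Pax2 0.0047 by library size, 0.0037 with no filter and 0.0485 with the GC offset; the cause was not tested. With 1 library left out Pax2 ranged from -0.1544 to 0.1121, Gfra1 from -0.128 to 0.2232, Wnt11 from -0.1304 to 0.215 and Etv4 from -0.1802 to 0.1994. Of the 80 called named genes, 60 passed in all 13 other scalings, filters and tests that kept the 4 libraries, and 25 in these and in the 4 fits that left out a library; the other 2 thresholds are not counted here. In the simulation at this depth and group size 72% of genes changed by 2-fold were recovered, so changes of that size can be missed.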

Other observations

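The gene families for this paragraph were chosen after the data were seen, by shared symbol stem, with 103 families of at least 15 tested genes and 206 one-sided Fisher exact tests. Of 350 tested genes with symbols that begin with Slc, most of them solute carriers, 57 were lower and 1 (Slc26a7) higher (adjusted p = 1.92e-23), and 44 of the 57 belong to none of the fixed lists. They include the urate and organic ion transporter genes Slc22a12 and Slc22a2, the sodium-glucose transporter gene Slc5a1 (log2 fold change -3.70, SE 0.32) and the amino acid transporter genes Slc6a18 (-3.02, SE 0.20) and Slc7a13 (-4.07, SE 0.39). Of 56 cytochrome P450 genes 8 were lower (adjusted p = 0.014), among them Cyp24a1, which degrades vitamin D hormone (-3.10, SE 0.39), and of 18 aldehyde dehydrogenase genes 5 were lower (adjusted p = 0.0108), among them Aldh4a1 (-1.30, SE 0.11). Of 22 keratin genes 5 were higher (adjusted p = 6.6e-06) and 1 (Krt7) lower. Genes are not independent replicates, so these p describe clustering of calls and not replication.

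Apart from that on the neighbourhood of Hnf1b, all tests in the next paragraphs concern patterns already seen in these data. The predictions for that test, for transcript length and for muscle genes outside the list were written before these tests were run. All other tests were chosen after their result was seen. The fall of proximal tubule genes in both mutant libraries is weighed first. The tables argue against muscle tissue or embryo sex in mutant 1 as the whole cause, since the list median is -2.53 without that library, against GC bias (-2.82 with the offset) and against length bias (-2.81 after the length trend was subtracted). A loss of nephrons of all segments alike would lower podocyte genes too, and the lowest podocyte member, Foxc2, is at -0.41, far above the bound of -1.40 set from the proximal median. A younger stage of the mutant kidneys stays open: the embryonic globin Hbb-y made up 0.436% and 0.269% of beta-like globin counts in mutants and 0.272% and 0.541% in controls, a difference of means of -0.0534 percentage points in overlapping groups. Fewer proximal tubule cells and lower expression per cell cannot be told apart in whole kidneys. The members' interquartile range of 2.16 against a median SE of 0.277 shows unequal folds but not their origin. An effect of the genotype itself stays open. By their labels the mutants differ from controls by the Cre, by a LacZ allele also carried outside the bud lineage, and by deletion in the bud. These parts of the genotype cannot be told apart here.

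Higher levels of Krt5, Krt14, Krt15, Krt4 and Krt17 in both mutant libraries are the second pattern. Tissue carried over with the muscle of mutant 1 is argued against by the fold changes without that library, the lowest of which is 3.38 (Krt15), while the muscle list median is then 0.01. Differentiated epidermis stays open. In mutant 1 and mutant 2, 6 suprabasal genes summed to 27.1 and 23.7 CPM, against 19.6 and 16.7 CPM in control 1 and control 2. Their excess over the higher control was 10.6% and 15.3% of that of Krt5. Log2 fold changes were 0.41 for Krt1, 0.49 for Krt10 and 1.27 for Lor, none of these 3 called. Krt10 and Lor were above both controls in both mutants. Krt1 was at 3.12 CPM in mutant 1 but at 1.42 CPM in mutant 2, below control 1 (1.85 CPM) and control 2 (1.54 CPM). Carried-over bladder or ureter urothelium stays open. Of 5 uroplakins, Upk3a (-5.08) and Upk2 (-1.26) were below both controls in both mutants. Upk1a (0.63) was above, and Upk1b (-0.38) and Upk3b (0.84) were neither. The 8 smooth muscle genes of ureter and bladder summed to 510 and 508 CPM in mutants against 455 and 494 CPM in controls. In mutant 1, the library with skeletal muscle transcripts, this sum held 146 CPM of Des. Des was at 73.5 CPM in mutant 2, 71.5 CPM in control 1 and 82.4 CPM in control 2. Over the 8 genes the median ratio of mutant 1 to the highest other library was 0.651, so the sum does not show more smooth muscle there. In mutant 2, Myh11, Actg2, Acta2, Cnn1 and Tagln were above both controls, Des and Synpo2 lay between them and Smtn was below both. Tagln was at 65.9 CPM in mutant 2, against 34.8 CPM in control 1 and 42.4 CPM in control 2. None of the 8 genes was called, so more smooth muscle in mutant 2 is not excluded. Another stratified epithelium and the genotype also stay open, untested.

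Skeletal muscle genes high in mutant 1 alone are the third pattern. Of 21 muscle genes outside the fixed list, 17 were over 4 times as high in mutant 1 as in the highest other library, with a median ratio of 11.2, among them Ckm at 120.1 CPM against at most 0.823 CPM. This is consistent with muscle carried over at dissection, and no biological explanation was tested.

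Within 5 Mb of Hnf1b 4 of 112 tested genes passed, which were Myo1d, AA465934, Taf15 and Car4 (3.57%, exact 95% interval 0.982% to 8.89%), against 3.54% elsewhere (one-sided Fisher exact test, p = 0.563); these counts are too few to decide about passenger variants beside the targeted allele.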
